A study of Mus musculus with 6 samples.

How the data were processed

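RNA was measured by sequencing of mRNA libraries from cultured primary mouse pulmonary endothelial cells of the C57BL/6 strain. Per the labels, cells at 80% confluence in an endothelial growth medium received water or 300 uM hydrogen peroxide (H2O2) for 6 hours, and each library was made from 100 ng of total RNA. The 6 libraries form a control group of 3 and an H2O2 group of 3. The labels number the libraries of a group 1 to 3 and do not say that they came from separate cultures or animals, so every p-value measures only the spread between these libraries, which may be technical.

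The deposited values are whole-number read counts per gene symbol, 1 table per library. Per the submitters' processing notes, bcl2fastq 2.17.1.14, cutadapt, STAR 2.5.3, HTSeq and DESeq2 were used with the mouse build mm10. The gene annotation and the strand setting of the counting were not given in the sources used here. Without a stated strand setting, reads of a gene and of an overlapping gene on the opposite strand cannot be told apart, and reads on near-identical copies of a gene can be set aside or split by the counting.

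The deposited count tables end with 5 HTSeq summary classes, which were left out of library sizes and tests. Reads with no feature were 5.18% ± 0.108 of all counted reads in controls and 5.20% ± 0.385 with H2O2 (SD, n = 3 each). Ambiguous reads were 3.21% ± 0.0475 and 3.26% ± 0.0639. Reads aligned to more than 1 place were 11.6% ± 0.124 in controls and 11.1% ± 0.0502 with H2O2. The classes for low alignment quality and for unaligned reads were 0 in all 6 libraries.

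Of 33006 genes in the tables, 12924 passed edgeR's filterByExpr and were tested. The test was edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) with TMM factors and treatment as the only term. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05, and each log2 fold change is H2O2 over control with its standard error (SE) from that fit. Normalised read counts (CPM) are the deposited counts scaled to a common library size with TMM factors.

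28 gene lists were fixed before the data were examined, as were the groups, the tests, the alternatives and the rule for named genes. The lists cover oxidative, integrated, heat shock, endoplasmic reticulum and p53 stress responses, inflammation, interferon, immediate early genes, metabolism, ribosomal proteins, cell cycle, DNA repair, apoptosis, histones, numbered zinc finger genes, endothelial identity and signalling, and markers of other cell types of the lung. Each list with at least 3 tested members was tested with camera on log2 CPM, with a preset inter-gene correlation of 0.01 and adjustment over the 26 lists tested. Camera with an estimated correlation and fry were run beside it. Counts of list members are given over all genes tested and adjusted over the list alone.

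The named genes are the 5 largest rises and 5 largest falls among genes that passed the test with a mean log2 CPM of at least 4 and with all H2O2 libraries on 1 side of all control libraries. To these were added up to 2 passing members with the smallest p of each pathway list, or its most abundant member where none passed, and the most abundant member of each marker list. Gene models without a standard symbol and pseudogenes were not eligible.

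Alternatives covered other scaling factors (DESeq2's size factors, upper-quartile factors, library size only), the tests of DESeq2 1.42.0 and limma-voom, looser and stricter filters on low counts, the replicate number as a block, and fits without each library in turn. Added after the data were seen were a per-library offset for transcript length and GC content, the same offset with the block, and scaling without ribosomal protein, mitochondrial and ribosomal RNA genes. The offset was a loess trend with a span of 0.3, fitted on genes outside the fixed lists. Transcript lengths and coordinates came from GENCODE M21, which uses the same assembly as mm10. Lengths were found for 99.1% of the tested genes.

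The methods were tested on simulated data for this comparison, drawn from the real means, dispersions and library sizes of the 12924 tested genes. Of the simulated genes, 12819 passed the filter again and were tested. edgeR's test called 8 of 49 genes changed 1.1-fold, 26 of 48 changed 1.2-fold, 37 of 49 changed 1.5-fold and 46 of 47 changed 2-fold. It also called 9 unchanged genes, which were 7.14% of its calls. In a simulated comparison of 12837 genes with a length trend in 3 libraries, 2183 genes were called without the offset and 4 with it. Camera called 0 of 20 unchanged lists of 20 genes and called the list shifted by 0.2 on the log2 scale, which passed with an estimated correlation too. The simulated genes varied independently of each other, so this does not cover lists of correlated genes. Among the real lists, the estimated correlation was 0.52 for ribosomal proteins and 0.77 for mitochondrially encoded transcripts.

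The depth was 22455388 to 27618679 gene counts per library, and the common biological coefficient of variation in edgeR was 3.01%. Changes of 1.1-fold were mostly missed in the simulation. It changed far fewer genes than the 2649 called in the real comparison, so its adjusted threshold was stricter. Its recovery therefore does not give the sensitivity of the real comparison. The groups rest on the labels alone, with no independent measure of the treatment used here. Splicing, isoforms and protein levels were not analysed here.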

Results

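The libraries address how the transcriptome of cultured primary pulmonary endothelial cells differs after 6 hours in 300 uM H2O2, an oxidant that cells detoxify with catalase, peroxiredoxins and glutathione peroxidases. Control libraries held 24349300 ± 1673160 gene counts and H2O2 libraries 26937100 ± 809535 (mean ± SD, n = 3 each). All pairs of libraries of a group differed by more than sampling noise, with a chi-square per degree of freedom of 1.64 to 11.8 over genes. The highest values were those of H2O2 replicate 3 with H2O2 replicate 1 (9.21) and with H2O2 replicate 2 (11.8). This measure gives most weight to abundant features, and Gm26924 took 3650 CPM (without TMM factors) in H2O2 replicate 3. In H2O2 replicates 1 and 2 it took 9806 and 11074. By correlation of log2 CPM these pairs (0.99600 and 0.99579) were close to the control pairs (0.99583 to 0.99611). The other H2O2 pair gave a chi-square per degree of freedom of 2.83. The first principal component held 33.9% of the variance of log2 CPM and separated the groups, and each library correlated best with a library of its own group.

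With H2O2, the list of ribosomal proteins was higher and the NF-kB, immediate early, NRF2, ATF4 and heat shock lists were lower by camera with its preset correlation, and 0 lists passed with an estimated correlation. Among genes with a standard symbol, pseudogenes left out, with a mean log2 CPM of at least 4 and all H2O2 libraries on 1 side of all controls, the largest rise was that of Rps14, from 234 ± 4.88 to 372 ± 28.2 CPM (1.59-fold), followed by Rpl9, Rpl19, Rps27 and Rps27a. All 5 encode proteins of the cytosolic ribosome. Under the same limits the largest fall was that of Avil, which encodes the actin-binding protein advillin, from 21.3 ± 0.915 to 11.4 ± 0.489 CPM (1.87-fold lower). Next were the neutrophil chemokine Cxcl2 (1.79-fold lower), the prostaglandin synthase Ptgs2 (1.70-fold lower), mmu-mir-6236 (1.69-fold lower) and the cytokine Il6 (1.64-fold lower). The feature mmu-mir-6236 is annotated as a microRNA, but the scaling without ribosomal RNA genes left it out among those genes. The source of its reads was not tested. It was not called by DESeq2's test and was less changed without H2O2 replicate 3. All values are means ± SD over 3 libraries per group.

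**Figure D1:**
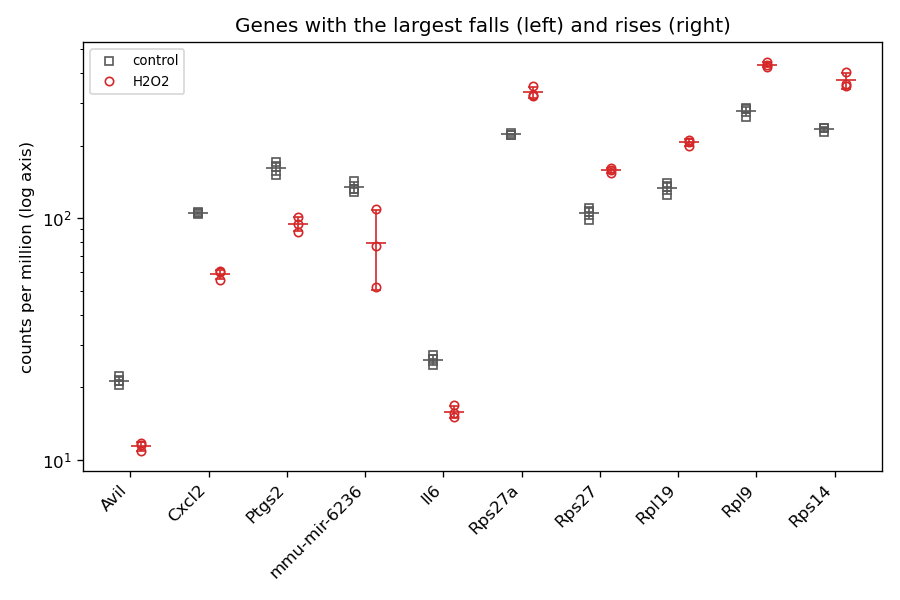
Normalised read counts (CPM) on a log axis for the genes with the largest falls and rises at a mean log2 CPM of at least 4, with squares for the 3 control libraries and circles for the 3 H2O2 libraries. The bars give the mean and SD of each group, and in each gene all H2O2 values lie on 1 side of all control values, with the widest spread in mmu-mir-6236 (79.4 ± 29.0 CPM with H2O2).

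Across the transcriptome, 2649 genes changed, 1254 higher and 1395 lower with H2O2. The changes were small: the median size among these genes was 13.2%, 595 changed by at least 1.2-fold, 89 by at least 1.5-fold and 24 by at least 2-fold. Of those 24 genes, 16 rose and 8 fell, and none had a mean log2 CPM of 4 or more. This count depended on the processing: it was 5 by DESeq2's test, 5 with the stricter filter and 47 with no filter on low counts. All 3 H2O2 libraries lay on 1 side of all 3 controls for 34.6% of the tested genes, where chance gives 10%. Of the fixed lists, 15 were called by camera, 6 higher and 9 lower, and 0 of them passed with an estimated correlation, where 9 lists had an unadjusted p under 0.05. Every fit that left out 1 library called fewer genes in both directions. Lower genes numbered 926 (without H2O2 replicate 1) to 1313 in place of 1395. Higher genes numbered 891 (without control replicate 2) to 1178 in place of 1254.

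**Figure D2:**
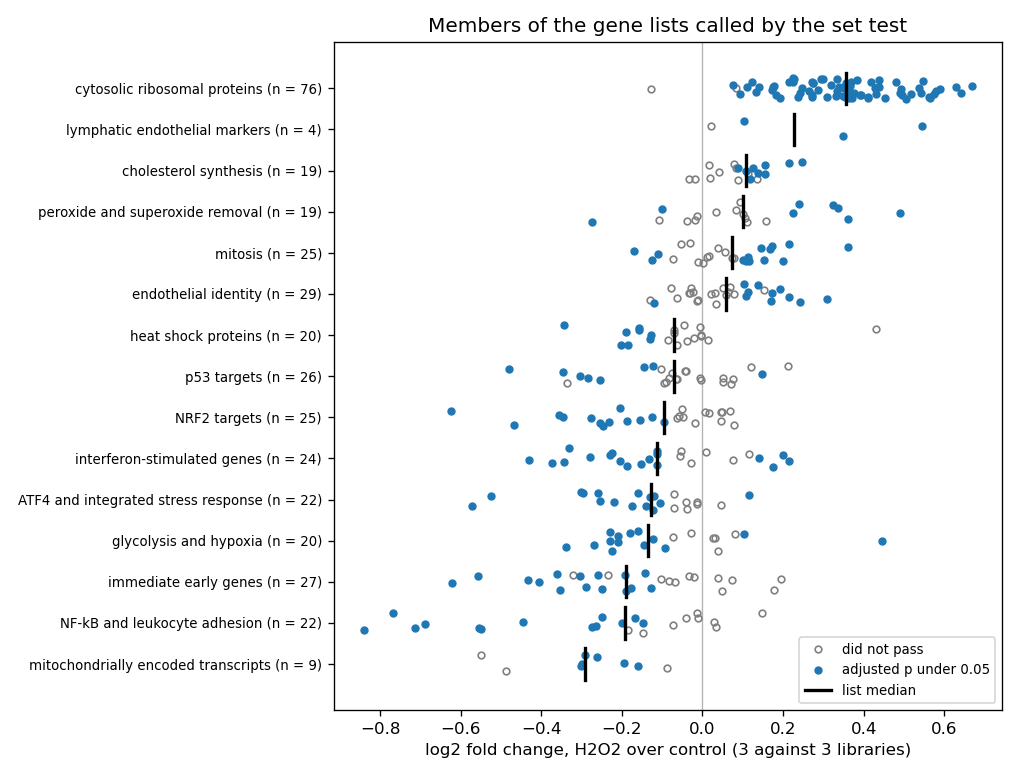
Log2 fold changes (H2O2 over control, 3 against 3 libraries) of the members of the 15 lists called by the set test, with filled points for members that passed edgeR's test. Black lines mark list medians, which run from -0.29 for mitochondrially encoded transcripts to 0.36 for cytosolic ribosomal proteins.

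Of the 76 cytosolic ribosomal protein genes tested, 74 rose and 0 fell, and adjusted over the list alone 75 rose and 1 fell. The median log2 fold change was 0.36, and camera gave an adjusted p of 6.5e-42 (adjusted p = 0.13 with an estimated correlation). Rpl9 rose by 0.64 (SE 0.0320) and the stalk protein gene Rplp0 by 0.54 (SE 0.0286) on the log2 scale, with adjusted p of 1.1e-13 and 3.4e-13 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Rpl21 (0.08) and Rpl24 (-0.13) did not pass. Ribosomal protein genes took 2.88% ± 0.0631 of gene counts in controls and 3.61% ± 0.0998 with H2O2 (SD, n = 3 each). These genes have many processed pseudogenes that can take or remove reads, so their single values are uncertain. Short transcripts in general lay higher with H2O2, and with an offset for transcript length and GC content, chosen after the data were seen, the list median was 0.23, with 66 members higher and 1 lower.

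**Figure D3:**
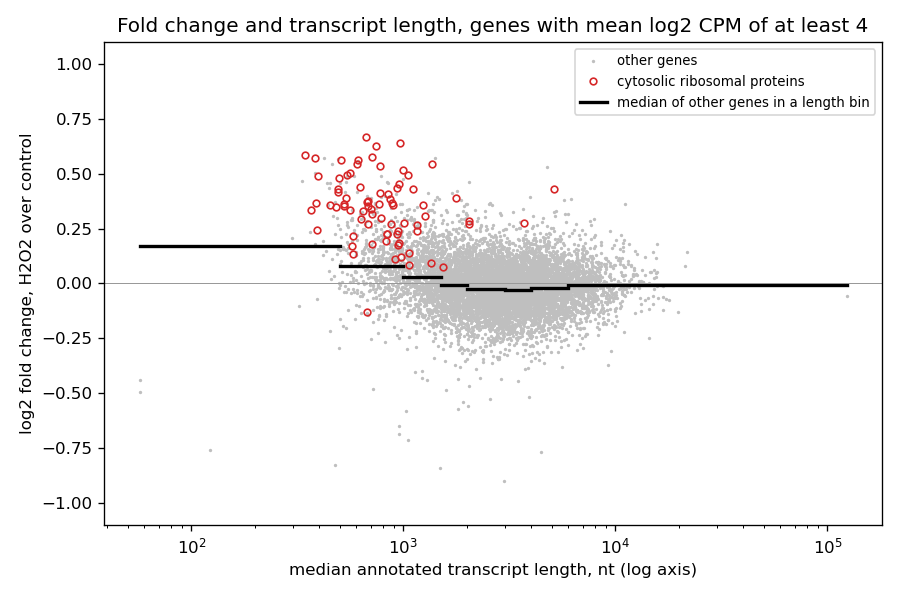
Log2 fold change (H2O2 over control) against median annotated transcript length on a log axis, for genes with a mean log2 CPM of at least 4. Black lines give the median of genes outside the ribosomal protein list per length bin, from 0.17 below 500 nt to -0.03 at 3000 to 4000 nt, and open circles mark the ribosomal protein genes (median 0.36).

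Inflammatory genes under NF-kB, the transcription factor that drives cytokine and adhesion genes in activated endothelium, were lower with H2O2. Of 22 tested members of that list, 13 fell and 0 rose (15 and 0 adjusted over the list alone), with a median log2 fold change of -0.19. Camera gave an adjusted p of 3.1e-07 (adjusted p = 0.13 with an estimated correlation). Cxcl2 fell from 105 ± 0.751 to 58.7 ± 2.75 CPM and its neighbour Cxcl1 from 238 ± 3.97 to 148 ± 7.38 CPM (SD, n = 3 each). In log2 terms these were -0.84 (SE 0.0390) and -0.69 (SE 0.0339), with adjusted p of 6.4e-14 and 1.1e-13 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Both chemokine genes lie on chromosome 5 (mm10, GENCODE M21), Cxcl2 at 90903871 to 90905938 and Cxcl1 at 90891241 to 90893115. Il6 lies on the same chromosome at 30013114 to 30019981, and Ptgs2 on chromosome 1 at 150100031 to 150108227. The adhesion gene Vcam1 fell by 0.15, whereas Icam1 (-0.07), Sele (-0.04) and Selp (0.03) did not pass.

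Immediate early genes, which cells induce within minutes of a stimulus, were lower as a group. Of 27 tested, 15 fell and 0 rose (17 and 0 adjusted over the list alone), with a median of -0.19 and an adjusted p of 3.1e-07 by camera (adjusted p = 0.11 with an estimated correlation). Ier3 fell from 163 ± 4.65 to 123 ± 5.43 CPM and the matricellular gene Cyr61 from 36.5 ± 2.48 to 24.7 ± 2.14 CPM. Egr1 fell by 0.62 and Atf3 by 0.35 on the log2 scale, and Fos (-0.32) did not pass.

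Among 24 interferon-stimulated genes, 14 fell and 4 rose, and the counts were the same adjusted over the list alone. The median was -0.11, with a camera adjusted p of 0.013 (adjusted p = 0.67 with an estimated correlation). Cxcl10, a chemokine for T cells, fell by 0.43 (SE 0.0497) and Ifit3, an antiviral effector, by 0.37 (SE 0.0468), while Irf7 (0.17), Bst2 (0.20), Oas1a (0.21) and Ifi44 (0.14) rose. The list's call ended without control replicate 2 (camera adjusted p = 0.051) and without control replicate 3 (0.053), and stood at 3.4e-05 to 0.053 over all fits that left out 1 library.

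Targets of NRF2, the transcription factor of the antioxidant response, were lower with H2O2: 13 of 25 fell and 0 rose, or 13 and 1 adjusted over the list alone, and 1 rose with upper-quartile factors. The median was -0.10 and camera gave an adjusted p of 1.7e-04 (adjusted p = 0.31 with an estimated correlation). The autophagy receptor Sqstm1 fell from 1636 ± 30.2 to 1183 ± 23.6 CPM (1.38-fold lower) and the haem oxygenase Hmox1 from 762 ± 17.1 to 595 ± 25.6 CPM (1.28-fold lower; SD, n = 3 each). Exons of a gene on the opposite strand cover 17.3% of the exon bases of Sqstm1. Srxn1, which reactivates oxidised peroxiredoxins, fell by 0.35, and Nqo1 (0.02) did not pass.

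Enzymes that remove peroxide and superoxide moved in both directions. Of 19 tested, 6 rose and 2 fell, also adjusted over the list alone, with a median of 0.10 and a camera adjusted p of 0.012 (adjusted p = 0.42 with an estimated correlation). The glutathione peroxidases Gpx1 (0.49, SE 0.0357) and Gpx4 (0.36, SE 0.0352) rose, as did Gpx3, Sod1, Prdx2 and Prdx4, whereas catalase (Cat, -0.10) and Prdx6 (-0.27) fell. The falls numbered 1 without control replicate 2 or 3, without H2O2 replicate 1 or 2, with each other scaling factor, with the stricter filter and by DESeq2's test. With the offset for length and GC content the list was not called (adjusted p = 0.17), and Gpx4 stood at 0.24.

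In the ATF4 list, genes of the integrated stress response to amino acid shortage and misfolded protein, 14 of 22 fell and 1 rose (15 and 1 adjusted over the list alone). The median was -0.13, with a camera adjusted p of 8.4e-07 (adjusted p = 0.11 with an estimated correlation). Ppp1r15a, which recruits a phosphatase to eIF2 alpha, fell from 140 ± 3.34 to 97.01 ± 0.376 CPM, and cystathionine gamma-lyase (Cth) from 112 ± 5.92 to 74.9 ± 4.14 CPM (SD, n = 3 each). Atf4 itself fell by 0.12 and Ddit3 by 0.30 on the log2 scale, and Vldlr rose by 0.11. The list had 0 rises without control replicate 1, 2 or 3, without H2O2 replicate 1 or 3 and by DESeq2's test.

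Heat shock proteins showed 8 falls and 0 rises among 20 genes, the same adjusted over the list alone, with a median of -0.07 and a camera adjusted p of 3.5e-04 (adjusted p = 0.11 with an estimated correlation). Hspa1b fell by 0.34 (SE 0.0469) and the co-chaperone Stip1 by 0.20 (SE 0.0280). With the offset for length and GC content, 12 fell and the median was -0.11. Chaperones of the endoplasmic reticulum split evenly, with 5 rises and 5 falls among 20 genes (7 and 7 adjusted over the list alone), and were not called (camera adjusted p = 0.52). Hspa5, the main chaperone of that compartment, fell by 0.30 (SE 0.0275) and the translocon subunit Sec61b rose by 0.29 (SE 0.0389), or by 0.16 with the offset. Without H2O2 replicate 1, 2 of these chaperones rose in place of 5, and without control replicate 2 this was 3.

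Of 26 p53 targets, 7 fell and 1 rose, also adjusted over the list alone, with a median of -0.07 and a camera adjusted p of 0.013 (adjusted p = 0.16 with an estimated correlation). The polo-like kinases Plk2 and Plk3 fell by 0.35 (SE 0.0295) and 0.30 (SE 0.0408), and Cdkn1a (-0.04), the cell cycle inhibitor under p53, did not pass. Without control replicate 2 the call ended (camera adjusted p = 0.052, against 0.0062 to 0.052 over all fits that left out 1 library) and 4 members were lower, as they were without H2O2 replicate 2 and by DESeq2's test. With the offset for length and GC content, 0 p53 targets rose, as without control replicate 1 or 3 or H2O2 replicate 1 or 2. Apoptosis regulators were not called (camera adjusted p = 0.80), with 2 of 20 higher and 4 lower, or 3 and 4 adjusted over the list alone. Without control replicate 3 or H2O2 replicate 1, 0 of them rose, and DESeq2's test called 1 rise and 2 falls. With upper-quartile factors, 4 rose and 4 fell. Cflar (-0.20, SE 0.0486) and Bcl2l1 (-0.15, SE 0.0316), which restrain apoptosis, both fell. Without H2O2 replicate 3, Cflar stood at -0.12, and DESeq2's test did not call it (adjusted p = 0.12, against 6.0e-07 to 0.12 over all alternatives).

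Glycolytic and hypoxia-responsive genes were lower: 12 of 20 fell and 2 rose (13 and 3 adjusted over the list alone), with a median of -0.13. Camera gave an adjusted p of 8.8e-04 (adjusted p = 0.11 with an estimated correlation). Hexokinase 2 (Hk2) fell by 0.34 (SE 0.0307) and the enolase Eno1 by 0.21 (SE 0.0277), while Pdk1 (0.10) and Ankrd37 (0.44) rose and Gapdh (0.08) and Ldha (0.03) did not pass. The rises numbered 1 without control replicate 1 or 3, without H2O2 replicate 1 or 3 and by DESeq2's test. Transcripts of the mitochondrial genome fell in 6 of 9 genes, or in 7 adjusted over the list alone, with 0 rises, a median of -0.29 and a camera adjusted p of 1.9e-03 (adjusted p = 0.48 with an estimated correlation). Among them were mt-Cytb (-0.29, SE 0.0421) and mt-Nd2 (-0.30, SE 0.0483), and DESeq2's test called 3 of the 9.

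Cholesterol synthesis genes rose in 9 of 19 cases and fell in 0 (11 and 0 adjusted over the list alone), with a median of 0.11 and a camera adjusted p of 1.7e-04 (adjusted p = 0.11 with an estimated correlation). Fdps rose by 0.22 (SE 0.0380) and Cyp51 by 0.16 (SE 0.0352), both enzymes of the pathway. Annotated exons of another gene on the same strand cover 26.7% of the exon bases of Fdps. Without control replicate 2, 5 members rose in place of 9.

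Endothelial identity genes were slightly higher: 10 of 29 rose and 1 fell (11 and 2 adjusted over the list alone), with a median of 0.06. Camera gave an adjusted p of 0.013 (adjusted p = 0.13 with an estimated correlation). Emcn, which encodes endomucin, rose by 0.24 (SE 0.0298) and Plvap, a protein of fenestral and caveolar diaphragms, by 0.17 (SE 0.0281). Pecam1 (0.10) and Tek (0.17) rose as well, Nos3, the endothelial nitric oxide synthase, fell by 0.12, and Cdh5 (0.06), Kdr (0.06), Tie1 (-0.01) and Erg (-0.03) did not pass. The falls numbered 3 without H2O2 replicate 3, 2 without control replicate 1, with the replicate block and by limma-voom, and 3 with the offset for length and GC content, where 13 rose. Of 4 lymphatic endothelial markers, Prox1 (0.35), Mmrn1 (0.54) and Flt4 (0.10) rose, so that 3 rose and 0 fell, also adjusted over the list alone (median 0.23; camera adjusted p = 0.010, and adjusted p = 0.13 with an estimated correlation). The most abundant of the 4, Lyve1, stood at 1855 ± 24.3 CPM in controls and 1884 ± 24.1 CPM with H2O2.

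Mitosis genes rose in 11 of 25 cases and fell in 3 (13 and 4 adjusted over the list alone), with a median of 0.07 and a camera adjusted p of 0.013 (adjusted p = 0.40 with an estimated correlation). The kinetochore genes Cenpf (0.36, SE 0.0358) and Cenpe (0.21, SE 0.0363) rose, and the kinases Plk1 (-0.17) and Aurka (-0.13) and the activator Cdc20 (-0.11) fell. The call ended without H2O2 replicate 3 (camera adjusted p = 0.065, against 0.012 to 0.065 over all fits that left out 1 library), and 7 members rose without control replicate 3. Without control replicate 2 or H2O2 replicate 2, 1 member fell in place of 3. DNA replication genes were not called (camera adjusted p = 0.34), with 1 of 26 higher and 7 lower, or 2 and 9 adjusted over the list alone, among them the helicase subunits Mcm3 (-0.19, SE 0.0302) and Mcm2 (-0.19, SE 0.0326). Without H2O2 replicate 1 or with the offset for length and GC content, 2 of them rose, and the falls ran from 5 (without control replicate 2) to 10 (without H2O2 replicate 3).

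The remaining pathway lists were not called. For Notch and angiogenic signalling, 1 of 19 rose and 6 fell (3 and 8 adjusted over the list alone; camera adjusted p = 0.23), including the growth factor Vegfa (-0.23, SE 0.0363) and the Notch ligand Jag1 (-0.17, SE 0.0334). Double-strand break repair had 4 of 25 higher and 3 lower, also adjusted over the list alone (camera adjusted p = 0.72), with Brca2 at 0.22 (SE 0.0386) and Xrcc6 at -0.23 (SE 0.0361). In the TGF-beta, BMP and matrix list, 5 of 24 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.80). Its median (0.01) and its mean (-0.03) differed in sign, and the test leaned up. Sparc rose by 0.21 (SE 0.0264) and Ctgf fell by 0.51 (SE 0.0817), though exons of a gene on the opposite strand cover 23.2% of the exon bases of Ctgf. Of 292 numbered zinc finger genes, 3 rose and 12 fell (0 and 3 adjusted over the list alone; camera adjusted p = 0.47), including Zfp36 (-0.36, SE 0.0659), an RNA-binding protein that destabilises cytokine mRNAs, and Zfp259 (-0.17, SE 0.0383). Without single libraries these counts were as low as 0 rises in the Notch list (without control replicate 3 or H2O2 replicate 1), 1 rise in the repair list (without control replicate 2 or H2O2 replicate 1), 3 rises (without control replicate 1 or 3 or H2O2 replicate 1 or 2) and 1 fall (without control replicate 2 or 3) in the matrix list, and 0 zinc finger rises (without control replicate 2) and 4 falls (without H2O2 replicate 1). With the offset for length and GC content, 4 Notch genes and 1 repair gene rose. The Notch rises numbered 3 with upper-quartile factors, and 2 by DESeq2's test and without H2O2 replicate 2. DESeq2's test called 1 rise in the repair list, and 0 rises and 6 falls among zinc finger genes.

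Replication-dependent histone genes, whose mRNAs mostly lack a poly(A) tail, had 1 of 45 higher and 0 lower (0 and 0 adjusted over the list alone) and were not called (camera adjusted p = 0.80). The gene that passed, Hist1h2ae, stood at 0.825 ± 0.0269 CPM in controls and 1.41 ± 0.169 CPM with H2O2, with exons of a gene on the opposite strand over 19.6% of its exon bases. It no longer passed without any 1 of the 3 controls or without H2O2 replicate 2 or 3, nor with the offset for length and GC content, at 0.65 in place of 0.77 on the log2 scale (adjusted p of 0.061 to 0.10 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 0.025 to 0.10 over all alternatives). Without H2O2 replicate 3, the list was called higher (camera adjusted p = 4.7e-08), with 7 members higher and 0 lower. Other fits went the other way without a call. Without H2O2 replicate 2, 0 members were higher and 2 lower (median -0.18, camera adjusted p = 0.25), and without control replicate 1, 0 were higher and 1 lower.

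Markers of lung cell types outside the endothelium did not pass edgeR's test. Epithelial (2 tested) and mesothelial (1 tested) markers were too few for the set test: Ager stood at 1.01 ± 0.297 CPM in controls and 1.16 ± 0.197 with H2O2, and Msln at 0.399 ± 0.161 and 0.299 ± 0.110 CPM. None of 3 fibroblast, 3 mural and 4 leukocyte markers passed edgeR's test, also adjusted over the list alone (camera adjusted p = 0.80, 0.99 and 0.44), but 1 fibroblast marker was lower without H2O2 replicate 2. For the fibroblast list the median (0.0006) and the mean (-0.08) differed in sign, as for the mural list (-0.09 and 0.02), and the fibroblast median ran from -0.21 (without control replicate 3) to 0.03 (without control replicate 2) over fits that left out 1 library. Over the same fits the mural median ran from -0.22 (without H2O2 replicate 2) to -0.01 (without H2O2 replicate 3). The fibroblast gene Dcn was at 22.3 ± 0.802 and 22.3 ± 1.44 CPM, the mural gene Pdgfrb at 1.67 ± 0.269 and 1.57 ± 0.196, and Cd68, a lysosomal protein abundant in macrophages, at 159 ± 3.52 and 166 ± 3.75.

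H2O2 replicate 3 stood apart from its group. On the second principal component it lay at 12.8, against -6.57 and -8.94 for H2O2 replicates 1 and 2. That component also set control replicate 1 (8.24) apart from control replicates 2 (-0.57) and 3 (-4.94). The histone gene Hist1h1e took 4.13 CPM in H2O2 replicate 3, against 13.6 to 16.6 in the other libraries, and a few abundant features were low there as well. The gene model Gm26924 took 3650 CPM, here without TMM factors, against 9806 to 11449 in the other 5 libraries, and mmu-mir-6236 took 52.4 against 76.4 to 141.7. Gm23935 (303.5 CPM) and Lars2 (273.0 CPM) were lowest in this library too. Both also fell between the groups, Gm23935 by 0.44 (SE 0.121) and Lars2 by 0.52 (SE 0.126) on the log2 scale. Their adjusted p were 0.0093 and 0.0039 in edgeR's quasi-likelihood test, with all 3 H2O2 libraries below all 3 controls. Gm26924 (-0.41, SE 0.191) did not pass. Gm26924, mmu-mir-6236, Gm23935 and Lars2 were left out of the scaling without ribosomal RNA genes, and Hist1h1e was not. The source of the reads of these features was not tested. Without H2O2 replicate 3, mmu-mir-6236 was at -0.53 in place of -0.76 on the log2 scale, and DESeq2's test did not call it (adjusted p = 0.066, against 1.6e-86 to 0.066 over all alternatives). The mitochondrial ribosomal RNA genes mt-Rnr1 (-0.65, SE 0.0482) and mt-Rnr2 (-0.49, SE 0.0504) fell, with all 3 H2O2 libraries below all 3 controls.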

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

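Tests chosen only after the result was seen were the fits with the length and GC offset, with and without the replicate block, and the scaling without ribosomal protein, mitochondrial and ribosomal RNA genes. For the 57 named genes, 952 of 961 values under an alternative stayed on their side of the threshold and 9 missed it. Of these values, 10 changed sign, of which 0 passed in either fit. Ager, Hist1h2ae, Msln and Pdgfrb had no value with the stricter filter and no adjusted p by DESeq2's test. For the 26 lists tested, 302 of 309 values stayed on their side under the alternative fits, which leave out camera with an estimated correlation and fry (below), 6 missed the threshold and 1 newly passed it. The mean of a list changed sign in 14 of these values, of which 0 were of a list called in either fit. The count of changed genes ran from 1826 to 2490 over fits that left out 1 library, higher genes from 891 to 1178 and lower genes from 926 to 1313, the lowest of these without H2O2 replicate 1. DESeq2's test called 2044 genes, of which 2032 were shared with edgeR's call in the same direction, and left 1754 genes without an adjusted p. The length and GC offset called 2577 genes and kept 2142 of the 2649 calls.

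Genes changed over 2-fold, 24 in edgeR's test, numbered 5 by DESeq2's test, 5 with the stricter filter and 47 with no filter on low counts. The filters change which low-count genes are tested. DESeq2's test left 1754 genes without an adjusted p, among them Pdgfrb at a mean log2 CPM of 0.76. Of the 24 genes, all but Rpph1, Gm22513, Gm26244, Sel1l3 and Il1f9 had a mean log2 CPM of 0.30 or less. Low counts may thus account for the loss by DESeq2's test, but the lost genes were not traced by name. Without 1 library the count of genes changed over 2-fold ran from 15, without control replicate 2, to 31.

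The 15 lists called became 0 with an estimated inter-gene correlation. For some lists the values argue against a higher correlation as the cause. Heat shock (-0.0034), endothelial identity (-0.0014), glycolysis (0.0026) and lymphatic markers (-0.27) had estimates below the preset 0.01 and still lost their calls. The other called lists had estimates above 0.01. In the simulation, whose genes varied independently, the shifted list had a camera adjusted p of 4.1e-30 with the preset correlation. With an estimated correlation its camera adjusted p was 0.0046. The estimated setting thus weakened a list of uncorrelated genes too, so a lost call does not by itself show correlated genes. The cause was not tested further in the real lists. The lists called numbered 14 by fry, which called the Notch list and left out the interferon and mitochondrial lists, 14 with the offset, and 13 to 15 without 1 library. With the replicate block, 2738 genes and 15 lists were called. The libraries share only a number: the deviations of same-numbered libraries from their group means correlated at 0.00, 0.03 and -0.03 over genes, and not every library correlated best with its own number.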

Other observations

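Tests chosen only after the result was seen were those of the 5 further lists below, of the length and GC offset, of the pseudogene copies, of the mislabelled library and of the exchange of labels. Cytosolic aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, fell in 19 of 20 genes and rose in 0, also adjusted over the list alone, with a median log2 fold change of -0.21. Nars fell by 0.28 and Sars by 0.26, and Dars (-0.03) did not pass. Camera gave an adjusted p of 3.1e-13 over these 5 lists (adjusted p = 0.15 with an estimated correlation). Nuclear-encoded respiratory chain subunits rose in 42 of 78 genes and fell in 3 (48 and 4 adjusted over the list alone), with a median of 0.16. With the length and GC offset, 32 rose and 10 fell, and the median was 0.07. Their camera adjusted p was 2.9e-11 (adjusted p = 0.15 with an estimated correlation), in contrast to the falls of the mitochondrially encoded transcripts. Mitochondrial ribosomal proteins rose in 23 of 74 genes and fell in 4 (23 and 6 adjusted over the list alone), with a camera adjusted p of 0.0048 (adjusted p = 0.45 with an estimated correlation) and of 0.70 with the offset, where 12 rose and 7 fell. Proteasome subunits rose in 8 of 37 genes and fell in 7 (9 and 9 adjusted over the list alone; camera adjusted p = 0.48). With the offset, 3 rose and 10 fell, and the list was called lower (camera adjusted p = 0.045, and adjusted p = 0.44 with an estimated correlation).

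Of the genes changed over 2-fold, those named here were singled out after their values were seen, and no class of genes was tested among them. Rpph1, the RNA of RNase P, had 58 to 64 counts in controls and 185 to 233 with H2O2, a log2 fold change of 1.58 (SE 0.131), though exons of another gene on its strand cover 73.0% of it. The snRNA genes Gm26244 (1.19) and Gm22513 (1.23) and the Y RNA Rny1 (1.79, on 2 to 19 counts per library) were higher too, and Gm22009, with 343 exon bases, was lower (-1.13). Gm22009 had 30 to 41 counts in controls and 24, 23 and 6 in H2O2 replicates 1, 2 and 3, so the size of its fall rests largely on H2O2 replicate 3. Of the 8 genes that fell over 2-fold, Sel1l3 had the most counts in every control, with 131 to 138 against 68 to 81 with H2O2. Reads of Xist numbered 1 to 9 and those of the Y-linked Ddx3y, Eif2s3y, Kdm5d and Uty 0 in all 6 libraries, where a count of 0 allows up to 3 counts of the library total.

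The joint rise of ribosomal protein genes was set against technical explanations. A trend in transcript length and GC content accounts for part of it at most, since the list median was 0.36 without and 0.23 with the offset, and 74 of the 76 genes lay above the median of their 10 length-matched neighbours. A shift of reads out of the not unique class was first tested by shares of reads and stayed open: the ribosomal protein share rose by 0.601 points, 0.124 more than the not unique share fell, within summed SDs of 0.306. A second test was then chosen because the first was undecided, and it argues against that shift as the whole cause, since the 9 ribosomal protein genes with 0 annotated pseudogene copies of at least 97% identity had a median of 0.41, against 0.37 for the 27 genes with 5 or more. A response of all mRNAs with a 5' terminal oligopyrimidine tract, the translational class that ribosomal protein mRNAs belong to, would raise its other members too. With the offset, 20 of them (3 higher, 6 lower) had a median of -0.021, which argues against a rise of the class as a whole. Without the offset they ran from -0.22 to 0.40, with 4 higher and 6 lower. A change in ribosomal protein mRNAs under H2O2 and a difference in how the libraries captured them remain possible. A shift of reads as part of the cause and an exchange of the group labels (below) remain possible too, and these were not told apart.

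The fall of stress and inflammatory genes goes against the textbook induction of NRF2, heat shock, ATF4, immediate early and NF-kB targets by peroxide. Of 115 tested members of these 5 lists, 62 fell and 1 rose, and the median was -0.13 without and -0.14 with the length and GC offset, which argues against a length trend. A single mislabelled library is unlikely, since 0 libraries correlated best with a library of the other group. An exchange of both group labels cannot be told apart from a response at 6 hours or from another difference between the groups. The groups rest on the labels alone, and the tables hold no other measure of the treatment. A response past its peak would account for these values only if it had fallen below the control level. That 0 NRF2 targets were higher with H2O2 (1 adjusted over the list alone) decides nothing, since these targets are part of the pattern itself. Enzymes that remove peroxide and superoxide moved in both directions, with 6 higher, as the labels would have it, and 2 lower. Camera gave an adjusted p of 0.012, of 0.42 with an estimated correlation and of 0.17 with the offset, so these enzymes do not decide on the exchange either. No biological explanation was tested, and libraries from earlier times would be needed to test a response past its peak.

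Splits of the 6 libraries into 3 against 3 number 10, too few for a share under 0.1, and in each case 1 split, the real one, gave a count as large. The real split called 2649 changed genes, 1254 higher, 1395 lower and 24 over 2-fold with edgeR, against at most 0 for each in the other splits, where up to 497 genes had an unadjusted p under 0.05 and limma-voom called 0. It called 15 lists, against at most 8. Every other split put libraries of both groups on each side, so a difference between the groups widened the spread within its sides. The low counts of those splits therefore do not show how many calls a comparison without any difference would give.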
